A study of Ruditapes philippinarum with 60 samples.

How the data were processed

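RNA of the digestive gland of Manila clams was hybridized to one-colour Agilent arrays with 14156 clam probes of 60 bases, which the authors scanned at 2 sensitivities. The labels describe glass aquaria with 1 l of seawater per animal, 7 days of acclimatization, and a daily change of water with ibuprofen and microalgae at 150000 cells per l. The controls received ethanol at 10 µl/l, which the labels give as the highest concentration used in the ibuprofen treatments. The amount of ethanol at each dose is not given. Comparisons with a dose may therefore also differ in ethanol, which was not separated from the drug. Arrays were grouped by treatment and exposure day as the sample titles give them.

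Per the file headers, the values of each array are processed signal intensities from Agilent Feature Extraction 9.5.1.1, on a linear scale, corrected for background and for spatial trends within the array and not normalized between arrays. The deposited series table holds intensities that the authors normalized between arrays by a method they do not state, and its columns share 1 maximum. In 58 of its 60 columns the order of the values is that of the array the label names. The columns of control day 1 replicates 2 and 4 hold each other's arrays, which belong to the same group. Cells of that table are empty for spots that were not found, which is 14.0 to 29.4% of a column. The other columns used, which are not a measured quantity, are indicators per spot set by Feature Extraction (per the file headers), such as whether it is well above background.

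The 459 positive and 77 negative control spots were left out. The log2 of the processed signal was taken and the 75th percentile of the array subtracted. Spots that Feature Extraction marked as non-uniform or as population outliers were set to missing, which concerned 327 spots of tested probes. A probe was tested if it was well above background on at least 4 of the 5 arrays of at least 1 group, which kept 9718 probes, or 68.7%.

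Differences were tested with limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 12 groups over all 60 arrays, which leaves 48 residual degrees of freedom, and the moderated test of limma was two-sided. P-values were adjusted by the method of Benjamini and Hochberg within each comparison, and probes with an adjusted p under 0.05 are called. The comparisons were each dose against the control at each day and on average over days, the difference of each dose's effect between days, 1000 minus 100 µg/l on average, the difference between days in the controls, and control day 7 minus day 1. These comparisons and the rule for named probes were set before the data were examined. The rule names, where the files give no gene name, at most the 2 called probes with the largest positive and the 2 with the largest negative log2 change in each comparison, and for the averages over days only probes with the same sign at all 4 days. For a probe that was well above background on no array of a group, the fold is given as a bound, computed against the dimmest signal that counted as well above background on each array of that group. Averages over days whose lower side includes such a group are given as a bound in the same way.

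The code was tested on simulated data of 9718 probes in which 200 probes per run were changed, in 3 runs. The simulated noise was normal and independent between probes and arrays, with no differences between slides. The shares below therefore test the code and need not hold for the real arrays. For 1000 µg/l at day 3, 1.99% of probes with a log2 change of 0.5 were recovered, 19.9% at 1 and 56.1% at 2, and 3.12% of the calls were false. For 1000 µg/l on average over days the shares were 17.9%, 52.2% and 86.4%, with 3.70% false calls. For the difference between days in the controls they were 0.50%, 15.9% and 55.6%, with 6.54% false calls. For the difference of the 1000 µg/l effect between days they were 0%, 6.96% and 36.9%, with 3.33% false calls.

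Alternatives were other background corrections and normalizations, the authors' own values, other filters, other limma settings and thresholds, a term for slide, for scan day or for replicate number, and leaving out each array in turn. The median change over all tested probes lay between -0.10 and 0.09 (log2) over the comparisons. It lay between -0.33 and 0.38 with normexp background correction and the 75th percentile. With slide as a fixed term 39 residual degrees of freedom remain.

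Tests of gene lists were not run. All 14156 probe descriptions read as unknown, the identifiers are contig names, and the 21 lists drawn up beforehand matched 0 probes.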

Results

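Gene expression was measured in the digestive gland of the Manila clam, the organ in which a bivalve digests and absorbs its food, after exposure to ibuprofen, a common anti-inflammatory drug. Clams were kept in water with the ethanol carrier alone, with 100 µg/l ibuprofen or with 1000 µg/l ibuprofen, and were sampled after 1, 3, 5 and 7 days. Each of the 12 combinations of treatment and day had 5 arrays, which makes 60 arrays in all. The labels do not state whether an array carried RNA of a single clam or of a pool, so the spread between arrays is the spread between whichever samples were hybridized. The sample titles do not name the aquarium of a clam. The p-values therefore do not measure a spread between aquaria, and an effect of the aquarium was not separated from that of the treatment.

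Each array held 14156 clam probes, and between 8316 and 9811 of them were well above background on an array. The 75th percentile of the processed signal lay between 399 and 2039 per array, with a median of 966.5. Between 0 and 2 clam probes per array were saturated. Log2 levels below are relative to the array's own 75th percentile, and each is a mean ± SD. After the filter on dim probes 9718 probes were tested. Pairs of arrays within a group correlated at a median r of 0.87 across probes, and pairs from different groups at a median of 0.86. Probes are not independent replicates, and the number of arrays limits the precision.

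The arrays lay on 10 slides, and the slides were not spread evenly over the treatments. 6 slides held both control and 100 µg/l arrays, 1 slide held both 100 and 1000 µg/l arrays, and 0 slides held both control and 1000 µg/l arrays. The 1000 µg/l arrays were on slides 6, 7, 8 and 10. The contrast between 1000 µg/l and the control could therefore be estimated within slides only by way of the 100 µg/l arrays of slide 10, which has 3 of them beside 4 arrays at 1000 µg/l. Within groups, 547 of the 9718 probes differed between slides in limma at the adjusted threshold. Estimates below are without a slide term unless it is named, and for each named probe a value with slide as a fixed term of the fit is also given. Slide as a random block used 1 correlation between arrays of a slide for all probes, 0.052. That fit also draws on differences between slides, so calls it kept do not exclude a difference between slides as their cause.

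The files pair no probe with a gene name, because every probe description reads as unknown. Probes are therefore given by their identifiers, with at most 2 that rose and 2 that fell in a comparison.

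The first question was whether 100 µg/l ibuprofen changed expression. On average over the 4 days, limma called 0 of 9718 probes, while 709 had an unadjusted p under 0.05 and the smallest adjusted p was 0.275. At day 1 limma called 0 probes, with 434 under the unadjusted threshold. At day 3 the count was again 0, with 589 under the unadjusted threshold. At day 7 limma called 0, with 349 under it. The effect of 100 µg/l differed between days at 0 probes in the limma test of that difference, and 769 probes had an unadjusted p under 0.05. Analysis of the authors' own values called 1 probe on average over days, 1 at day 1 and 2 for the difference between days.

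At day 5 of 100 µg/l, 75 probes were called, of which 68 were higher than in the control and 7 were lower. The probe ruditapes_s40094_S (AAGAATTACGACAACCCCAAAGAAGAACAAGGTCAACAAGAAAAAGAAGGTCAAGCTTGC) rose from -4.38 ± 0.35 to -1.37 ± 1.66 (SD, n = 5 in each group), a log2 change of 3.01 ± 0.71 (SE) with an adjusted p of 0.0323 in limma. It was higher in 5 of 5 arrays, and the slide term lowered the change to 1.15 ± 0.60. The probe NEW_ruditapes_c8544_AS (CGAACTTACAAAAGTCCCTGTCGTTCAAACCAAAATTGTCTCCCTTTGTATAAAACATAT) was well above background on 4 of 5 arrays at 100 µg/l and on 0 of 5 control arrays, so that its rise was at least 1.78-fold, with an adjusted p of 0.00593 in limma. Its adjusted p was 0.172 under the slide term, which raised the SE of its log2 change from 0.52 to 0.79 and did not make the estimate smaller. The adjusted p was 0.0051 with slide as a random block and 0.00164 with a scan day term. Over 14 alternatives, leaving out single arrays aside, the call held in 9. The control level of this probe was -8.94 at day 5, lower than -7.38, -7.57 and -7.71 at days 1, 3 and 7. None of these control levels was well above background. The probe ruditapesP_c3754 (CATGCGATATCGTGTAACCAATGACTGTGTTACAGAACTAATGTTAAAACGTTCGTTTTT) went from 2.27 ± 0.65 in the control to 0.25 ± 0.87, and fell by 2.02 ± 0.47 on the log2 scale in 5 of 5 arrays, with an adjusted p of 0.0323. The probe ruditapes2_c97_S (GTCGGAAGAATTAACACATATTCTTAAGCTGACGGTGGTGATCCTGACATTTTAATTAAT) fell by 1.52 ± 0.36 in 5 of 5 arrays, with an adjusted p of 0.0346. Under the slide term their changes were -2.49 ± 0.71 and -2.08 ± 0.55, with adjusted p of 0.512 and 0.347. When 1 of the 10 arrays was left out, the calls of these 4 probes held in 4, 10, 7 and 4 of 10 fits, in the order given. The fit with slide called 0 probes at day 5, and slide as a random block called 5. With 1 of the 10 arrays left out, the count of 75 became 2 to 167. Normexp background correction with the 75th percentile gave 0.

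The same question was asked of 1000 µg/l. On average over the 4 days, 106 probes were called, of which 59 were higher and 47 lower than in the control. Of these 106 probes, 78 had changes of the same sign at all 4 days, which choosing them by their average favours. The slide term left 0 calls, the median change of the 106 probes in the called direction went from 0.68 (median SE 0.17) to 0.44 (median SE 0.60), and slide as a random block called 31.

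The probe with the smallest adjusted p on average over days was ruditapesP_c17047 (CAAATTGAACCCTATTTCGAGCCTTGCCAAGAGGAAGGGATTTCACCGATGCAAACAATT), which the rule for named probes gives at day 5 and whose average is given here because its values were seen to stand out. In the controls its level was -0.58 ± 0.26 at day 1, -0.37 ± 0.39 at day 3, -0.16 ± 0.18 at day 5 and 0.09 ± 0.44 at day 7 (SD, n = 5). At 1000 µg/l it was 0.80 ± 0.16, 1.65 ± 0.51, 1.503 ± 0.78 and 1.75 ± 0.57 on the same days. The average change was 1.68 ± 0.16 (SE) on the log2 scale, or 3.2-fold, with an adjusted p of 4.24e-10 in limma. By day, the change was 1.38 at day 1 (adjusted p 0.183), 2.02 at day 3 (8.67e-04), 1.66 at day 5 (0.032) and 1.66 at day 7 (0.0111). At each day the lowest array at 1000 µg/l was above the highest control array. At 100 µg/l the average change was 0.29 ± 0.16, with an adjusted p of 0.732. Under the slide term the average change at 1000 µg/l was 0.71 ± 0.57, with an adjusted p of 0.845, so both a smaller estimate and a larger error ended the call. Within slide 10 the probe averaged 1.14 ± 0.61 in the 4 arrays at 1000 µg/l and 0.55 ± 0.80 in the 3 arrays at 100 µg/l (exact permutation test, one-sided p 0.2).

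**Figure D1:**
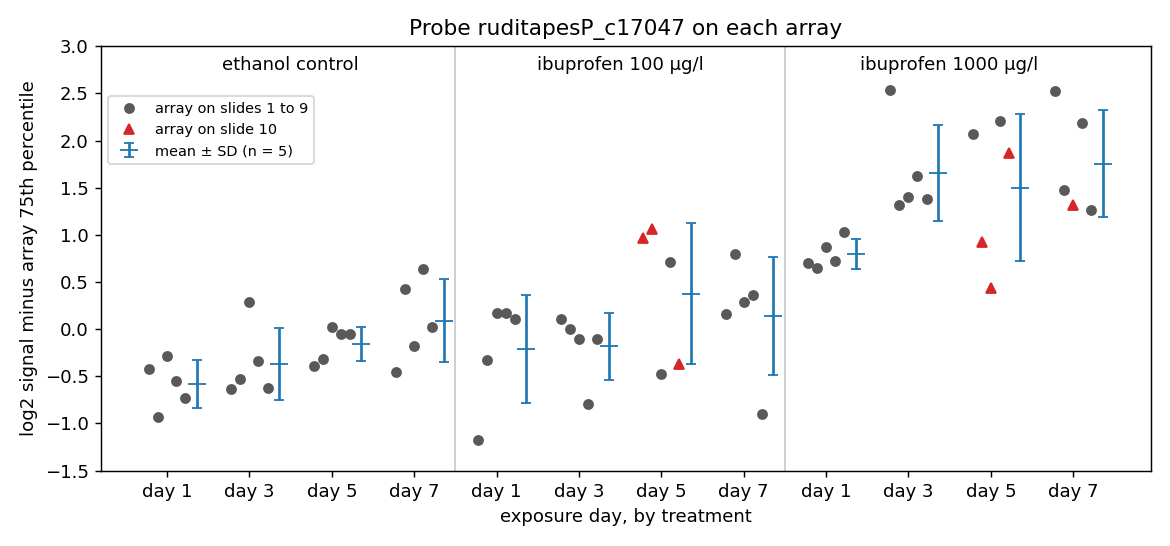
Level of the probe ruditapesP_c17047 on each of the 60 arrays, as log2 signal minus the array's 75th percentile (vertical axis), by treatment and exposure day (horizontal axis), with arrays of slide 10 as red triangles and the mean ± SD of each group of 5 in blue. The group means at 1000 µg/l lie between 0.80 and 1.75, and those of the controls between -0.58 and 0.09.

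By the rule for named probes, the largest changes at 1000 µg/l on average over days were the following. The probe ruditapesP_lrc10183 (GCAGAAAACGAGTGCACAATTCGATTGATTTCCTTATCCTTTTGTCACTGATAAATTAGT) was at least 6.70-fold higher, with an adjusted p of 0.0439, a bound because it was well above background on 0 of 5 controls at day 1 and at day 3. It was well above background on 10 of 20 arrays at 1000 µg/l and on 2 of 20 control arrays, and 13 of the 20 lay above the control mean of their day. The probe ruditapesP_c15642 (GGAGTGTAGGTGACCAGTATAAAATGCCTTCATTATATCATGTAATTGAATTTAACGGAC) rose by 4.10 ± 1.02, with an adjusted p of 0.0317, and 18 of 20 arrays lay above the control mean of their day. ruditapesP_c15642 was well above background on 18 of 20 arrays at 1000 µg/l and on 8 of 20 control arrays. The size of its change therefore rests partly on control levels near background. Both of these probes changed sign with slide in the fit, to -1.67 ± 4.92 and -1.37 ± 3.90. The probe ruditapesP_c20843 (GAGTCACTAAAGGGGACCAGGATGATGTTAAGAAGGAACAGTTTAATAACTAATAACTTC) fell by 2.79 ± 0.67 with an adjusted p of 0.0244, in 16 of 20 arrays, and its change with slide in the fit was -0.29 ± 2.41. The probe ruditapesP_c2751 (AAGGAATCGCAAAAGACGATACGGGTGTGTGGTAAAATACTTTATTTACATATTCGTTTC) was at least 2.26-fold lower, with an adjusted p of 0.0031 and in 17 of 20 arrays, and with slide in the fit its estimate was not smaller but the SE was 1.74 in place of 0.47 (adjusted p 0.704). It was well above background on 13 of 20 control arrays and on 5 of 20 arrays at 1000 µg/l, with 0 of 5 at day 3 and at day 7. When 1 of the 40 arrays was left out, ruditapesP_lrc10183 was called in 17 of 40 fits, ruditapesP_c15642 in 33, and the other 2 in all 40.

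At day 1 of 1000 µg/l, 2 probes were called in limma. The probe NEW_ruditapes_c1652_AS (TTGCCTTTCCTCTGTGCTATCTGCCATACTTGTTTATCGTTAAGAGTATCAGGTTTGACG) rose from -6.81 ± 0.78 to -4.34 ± 1.39, a change of 2.46 ± 0.48 with an adjusted p of 0.0291 and in 5 of 5 arrays. It was well above background on 4 of 5 arrays at 1000 µg/l and on 2 of 5 control arrays, the slide term gave 1.39 ± 1.02, and another background correction (normexp) gave -0.22, which is 0.11 relative to the median of all probes under that correction. The probe ruditapes_lrc34111_S (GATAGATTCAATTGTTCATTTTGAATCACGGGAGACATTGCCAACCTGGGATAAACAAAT) fell by 2.99 ± 0.59 with an adjusted p of 0.0291, in 4 of 5 arrays, and its change with slide in the fit was -3.79 ± 1.36 (adjusted p 0.831). ruditapes_lrc34111_S was well above background on 3 of 5 arrays at 1000 µg/l and on 5 of 5 control arrays. In fits that each left out 1 of the 10 arrays, each of the 2 probes was called in 2 of 10.

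At day 3 of 1000 µg/l, 140 probes were called, of which 45 were higher and 95 lower. The slide term left 0 of them and slide as a random block called 31. The probe ruditapes_lrc15418_S (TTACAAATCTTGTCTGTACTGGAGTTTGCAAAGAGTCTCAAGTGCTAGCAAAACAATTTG) was well above background on 5 of 5 arrays at 1000 µg/l and on 0 of 5 control arrays, and was at least 69.3-fold higher (adjusted p 0.027). Its level was -0.89 ± 1.10 at 1000 µg/l and -1.64 ± 0.82 at 100 µg/l (SD, n = 5). This probe also varied between well above and near background elsewhere: it was well above background on 4 of 5 controls at day 1 and at day 5, and on 1 of 5 arrays at 1000 µg/l on day 1. Its call was kept in 4 of 10 fits that each left out 1 array, and under the slide term its estimate was not smaller but the SE was 4.16 in place of 1.77, with an adjusted p of 0.535. The probe ruditapesP_lrc25075 (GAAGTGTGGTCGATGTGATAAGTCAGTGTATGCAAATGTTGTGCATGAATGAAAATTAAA) was at least 10.9-fold higher (adjusted p 0.0472), again on 5 of 5 arrays against 0 of 5. This probe varied elsewhere too: it was well above background on 3 of 5 controls at day 1 and 2 of 5 at day 7. At 1000 µg/l on day 5 it was well above background on 1 of 5 arrays. Its call was kept in 0 of 10 such fits, and under the slide term its estimate was smaller and the SE was 3.14 in place of 1.31, with an adjusted p of 0.822. The probe ruditapes_c5739_S (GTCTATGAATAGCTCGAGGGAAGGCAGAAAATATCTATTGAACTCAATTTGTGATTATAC) went from 0.77 ± 1.59 to -4.41 ± 4.51, and fell by 5.18 ± 1.41 on the log2 scale with an adjusted p of 0.0472, in 5 of 5 arrays. ruditapes_c5739_S was well above background on 3 of 5 arrays at 1000 µg/l and on 5 of 5 control arrays. Its levels at 1000 µg/l ranged from -9.48 to 0.68, so the size of the fall rests partly on levels near background. It was called in 3 of 10 such fits, and the slide term gave -3.32 ± 3.09 (adjusted p 0.813).

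At day 5 of 1000 µg/l, 2 probes were called in limma, both higher. ruditapesP_c17047 is described above. The probe ruditapesP_c7539_1 (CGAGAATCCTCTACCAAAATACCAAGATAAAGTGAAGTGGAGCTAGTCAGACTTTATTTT) rose from -1.48 ± 0.25 to -0.27 ± 0.21, a change of 1.21 ± 0.24 with an adjusted p of 0.032 and in 5 of 5 arrays. The slide term gave 0.91 ± 0.47 with an adjusted p of 0.937, and each of the 2 probes was called in 3 of 10 fits that left out 1 array.

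At day 7 of 1000 µg/l, 46 probes were called, of which 18 were higher and 28 lower. The slide term left 0 of them. The median SE went from 0.29 to 0.57, and the median change in the called direction from 1.21 to 1.15. Under the slide term 46 of 46 probes kept their direction, 19 changed at least as much and the others less. Slide as a random block called 24 probes. The probe ruditapesP2_c79_1 (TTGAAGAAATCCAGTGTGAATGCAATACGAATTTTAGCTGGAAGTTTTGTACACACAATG) rose from -0.45 ± 0.45 to 1.33 ± 1.00, a change of 1.79 ± 0.39 (adjusted p 0.021, higher in 5 of 5 arrays), and with slide in the fit of 1.79 ± 0.81 (adjusted p 0.649). The probe ruditapesP2_c567_1 (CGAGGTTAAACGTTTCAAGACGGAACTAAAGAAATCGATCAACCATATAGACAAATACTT) rose from -3.12 ± 0.38 to -1.33 ± 0.43 with the same adjusted p in limma, and the slide term gave 0.64 ± 0.76. Each of these 2 probes was called in 6 of 10 fits that left out 1 array. The probes NEW_ruditapes_s34828_S (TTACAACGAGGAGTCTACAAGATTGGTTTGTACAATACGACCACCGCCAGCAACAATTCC) and NEW_ruditapes_s34828_AS (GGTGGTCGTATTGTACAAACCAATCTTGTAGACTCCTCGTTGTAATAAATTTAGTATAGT) share 45 bases on opposite strands. The first fell by 4.06 ± 1.01 (adjusted p 0.0491) and the other fell by 3.75 ± 0.83 (adjusted p 0.0221), each in 5 of 5 arrays. Both were well above background on 2 of 5 arrays at 1000 µg/l and on 5 of 5 control arrays, and with slide in the fit their changes were -1.16 ± 2.01 and -1.03 ± 1.61. The first was called in 1 of 10 fits that left out 1 array, and the other in 4 of 10.

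**Figure D2:**
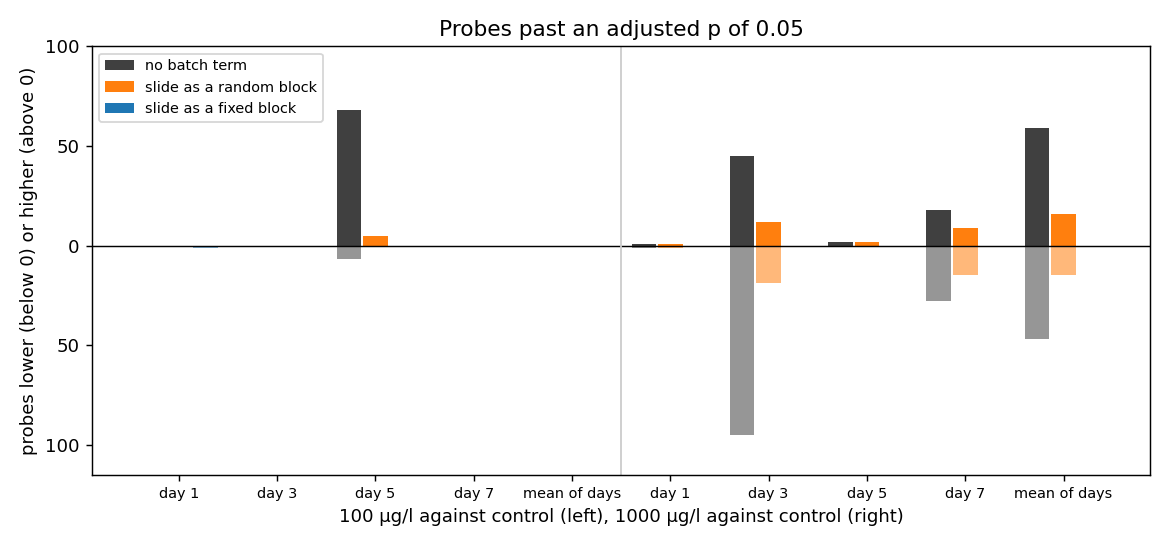
Number of probes past an adjusted p of 0.05 (vertical axis), higher than the control above the 0 line and lower below it in a lighter shade, at each exposure day and on average over days (horizontal axis). Bars give the fit with no batch term, with slide as a random block and with slide as a fixed block; the last called 1 probe at day 1 of 100 µg/l and 0 probes elsewhere.

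The effect of 1000 µg/l differed between days at 98 probes in the limma test of that difference, with a smallest adjusted p of 0.00806. Of the 45 probes higher at day 3 and the 18 higher at day 7, 2 were shared, where independent lists would share 0.0833, and of the 95 and 28 lower, 1 was shared, where independent lists would share 0.274. Under the slide term 0 probes passed.

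Whether the doses differed from each other was tested by the 1000 µg/l average minus the 100 µg/l average. limma called 221 probes, of which 92 were higher at 1000 µg/l and 129 lower, and the slide term left 0. The probes ruditapesN_c28432 (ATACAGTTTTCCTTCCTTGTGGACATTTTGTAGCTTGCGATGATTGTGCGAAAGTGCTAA) and ruditapesP_c25912_1 (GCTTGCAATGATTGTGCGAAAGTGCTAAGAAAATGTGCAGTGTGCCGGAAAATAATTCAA) share a stretch of 21 bases. The first was higher by 3.00 ± 0.54 on the log2 scale, with an adjusted p of 0.0011 and in 19 of 20 arrays. It was well above background on 17 of 20 arrays at 1000 µg/l and 5 of 20 at 100 µg/l, and with slide in the fit it was higher by 5.66 ± 1.80 (adjusted p 0.6). The other was at least 2.67-fold higher, with an adjusted p of 0.00325 and in 17 of 20 arrays, and with slide in the fit its estimate was not smaller but the SE was 1.81 in place of 0.54 (adjusted p 0.6). The probe ruditapesP_c5449 (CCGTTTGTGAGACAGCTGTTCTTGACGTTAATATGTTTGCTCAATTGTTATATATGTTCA) was lower, at -3.43 ± 0.91 with an adjusted p of 0.0305 and in 17 of 20 arrays, and changed sign with slide in the fit, to 2.90 ± 2.88. The probe NEW_ruditapes_lrc32249_S (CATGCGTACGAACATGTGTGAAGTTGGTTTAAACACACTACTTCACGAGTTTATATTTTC) was lower, at -2.88 ± 0.57 with an adjusted p of 0.00281 and in 19 of 20 arrays. NEW_ruditapes_lrc32249_S was well above background on 12 of 20 arrays at 1000 µg/l and on 20 of 20 at 100 µg/l. Its change under the slide term was -4.17 ± 1.99, with an adjusted p of 0.754. When 1 of the 40 arrays was left out, ruditapesP_c5449 was called in 34 of 40 fits and the other 3 probes in all 40.

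Change over time without the drug was tested in the ethanol controls. Expression differed between the 4 days at 55 probes in limma, with a smallest adjusted p of 0.00753 and 1625 probes under an unadjusted p of 0.05. The slide term left 0 of the 55. The days of the controls were not spread evenly over the slides, so differences between slides could enter this count. Between day 7 and day 1 of the controls limma called 0 probes, with 1035 under the unadjusted threshold and a smallest adjusted p of 0.24. Analysis of the authors' own values called 1 probe there.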

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

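Several tests in this part were chosen after results had been seen. They include the comparison of slide means for ruditapesP_c17047 and the medians of called sets with and without the slide term. The fits with slide as a random block, with a scan day term and without slide 10 are also among them. The patterns weighed below were themselves picked from the results, so every test of them concerns values already seen. For ruditapesP_c17047 this holds for the covariate, the comparison within slide 10 and the scan day comparison. A criterion stated beforehand for this probe can only have preceded its test, since the probe was chosen for its values.

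A sample far from the others of its group appeared 11 times among 96 group values tested by Dixon's ratio for 5 samples, and chance gives about 1 in 20. The 75th percentile of control day 3 replicate 4 was 1632, against 978 to 1073 in the other 4 arrays. For ruditapesP_lrc10183 the log2 level was -4.95 in control day 5 replicate 4, 3.08 in control day 7 replicate 3 and 3.73 in 1000 µg/l day 3 replicate 1, each far above its group. It was -8.78 in 1000 µg/l day 5 replicate 1, far below its group. For ruditapesP_c15642 the level was 0.34 in control day 7 replicate 2, far above its group, and -7.58 in 100 µg/l day 5 replicate 5 and -7.74 in 1000 µg/l day 5 replicate 2, both far below. ruditapesP_c20843 stood at 0.97 in control day 3 replicate 2, above its group. ruditapesP_c17047 stood at -0.80 in 100 µg/l day 3 replicate 4, below its group, and at 2.54 in 1000 µg/l day 3 replicate 1, above it. 4 of the 11 values belong to ruditapesP_lrc10183 and 3 to ruditapesP_c15642, probes that were near background on some arrays of a group and bright on others.

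A difference between days in the effect of 1000 µg/l was also found, at 98 probes, by the test of that difference itself in limma. Random splits of the same arrays gave as many in 1 of 100, the real one, and the highest other gave 2. These splits moved single arrays without regard to slide, so they cannot exclude a chance difference between slides. They exchanged control and 1000 µg/l arrays within each day, which also removes an effect that is equal on all days. The splits therefore do not test a difference between days by itself. The slide term left 0 probes, with slide as a random block 35, and without slide 10 0, and what ended these calls was not tested.

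Chance was examined in the same way for every comparison, with 100 splits that include the real one. Only the real split reached its count for 100 µg/l at day 5 (75 real, 29 highest other, 1 of 100 as many). The same held for 1000 µg/l at day 3 (140, 7, 1 of 100), day 7 (46, 5, 1 of 100) and on average (106, 2, 1 of 100). It also held for 1000 minus 100 µg/l (221, 5, 1 of 100) and for the days of the controls (55, 8, 1 of 100). Treatments and days were not spread evenly over the slides, and the splits ignored slide. They therefore speak against a chance division of single arrays and cannot exclude a chance difference between slides. Chance cannot be excluded for the count of 2 at day 1 of 1000 µg/l, where 15 of 100 splits gave as many and the highest other gave 201. Nor can it for the count of 2 at day 5 of 1000 µg/l, where 8 of 100 gave as many and the highest other gave 4, which is a test of the count and not of either probe. For the comparisons with 0 probes all 100 of 100 splits give as many. Their highest others were 45 for 100 µg/l at day 1, 274 at day 3, 3 at day 7, 32 on average and 4 for the difference between its days, and 2 for control day 7 minus day 1. The splits with 45 and 274 probes, where the real counts were 0, and with 201, where it was 2, point to a structure of the samples. The split with 45 had all 3 arrays of slide 9 on 1 side, and the split with 274 had all 4 arrays of slide 2 on 1 side. The split with 201 had arrays of slides 7 and 8 on both sides. In the fit with slide, 100 µg/l called 1 probe at day 1 and 0 at day 3, and 1000 µg/l called 0 at day 1.

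The first pattern weighed is the set of 106 probes at 1000 µg/l on average over days. With each array's 75th percentile as a covariate the median change kept 1.01 of its value, between 0.978 and 1.01 when any 1 array was left out. That percentile had already been subtracted. Its group means overlapped, at 800 to 1198 in the controls and 821 to 1154 at 1000 µg/l. The covariate could therefore hardly lower the change, and this test decides little about the strength of hybridization. A difference between slides stays open. Within slide 10, the 319 probes called without that slide differed between 1000 and 100 µg/l by a median of 0.19 in the called direction, and 3 of the 35 relabelings of its 7 arrays reached this. The median change by which these probes had been called was 0.75, against the controls over 4 days, and choosing the probes by it favours a large value. The slide 10 value compares 1000 µg/l at days 5 and 7 with 100 µg/l at day 5, so these medians are not like for like. The criterion stated beforehand for slide as the whole cause, at least 0.05 of the relabelings, was met, but a threshold missed with 7 arrays does not show that the arrays did not differ. An effect of ibuprofen and a difference between slides cannot be told apart for this set, because slides 6, 7 and 8 hold only 1000 µg/l arrays.

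The next pattern is the set of 75 probes at 100 µg/l on day 5. 3 of the 5 arrays at 100 µg/l were on slide 10 and 3 of the 5 controls on slide 9. Among the 1000 µg/l arrays of days 5 and 7, those on slide 10 differed from the others by a median of 0.57 in the called direction at these probes, which 1 of 50 relabelings reached, the real one, and 93.3% of the probes went that way. Among the day 1 arrays of the control and 100 µg/l groups, those on slide 9 differed by a median of -0.56, against the called direction, and 2 of 50 relabelings lay as low. Both differences between slides were measured on arrays outside this comparison, and they could produce part of the median called change of 1.24. The 2 arrays at 100 µg/l that were not on slide 10 still lay at a median of 0.86 in the called direction, but they helped to choose the probes. With the slide term the median change in the called direction went from 1.24 (median SE 0.29) to 0.66 (median SE 0.39), so smaller estimates and larger errors both ended the calls, and 0 were left. All 75 kept their direction and 13 changed at least as much, among them both named probes that fell. The average net signal of the negative control spots was 21.1, 19.2 and 19.3 on the 3 arrays at 100 µg/l of slide 10. On the day 5 controls it lay between 13.2 and 17.1. Normexp background correction gave 0 calls with the 75th percentile and more with quantile normalization. What background contributed to the 75 calls was not tested. Differences between slides are a candidate cause of part of the change, and an effect of the drug at this dose stays open.

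The last pattern is the rise of ruditapesP_c17047 at 1000 µg/l. With the 75th percentile as a covariate the change was 1.69 ± 0.16 against 1.68 without. For the reason given for the first pattern, this decides little about a change of the array's overall signal. Variation between slides stays open. With slide means as the values, and slide 10 entered by its 4 arrays at 1000 µg/l alone, the 4 slides with 1000 µg/l arrays lay at 1.14 to 1.96 and the other 6 at -0.55 to 0.01. The mean of all 7 arrays of slide 10 was 0.89. The real choice of slides was the 1 of 210 with the largest difference, but the probe had been picked from 9718 because it stood out, and chance alone would give about 46.3 probes with that outcome (97 had it), so this comparison decides nothing. A batch that coincides with the dose stays open too, since the slides of the 1000 µg/l arrays may have been processed apart. Within slide 10 the difference was 0.59, and 7 of 35 relabelings reached it, so the criterion stated beforehand for slide as the whole cause was met, though with 7 arrays this does not show that there was no difference. On the 1 scan day with all 3 treatments, the probe was at -0.16 ± 0.26 in 4 controls, 0.14 ± 0.05 in 2 arrays at 100 µg/l and 1.19 ± 0.30 in 6 at 1000 µg/l, but the 1000 µg/l arrays were on a slide of their own. With a scan day term the change was 1.11 ± 0.27, with an adjusted p of 0.318. A response to ibuprofen and a batch of slides cannot be told apart for this probe.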

How the results depend on the processing

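Slide as a random block, a scan day term, the fit without slide 10 and the median changes under the slide term were chosen after seeing the data; the other alternatives were fixed before the data were examined. Counts are of probes past the adjusted threshold in limma, and a count that stayed within 1.5-fold of the reported one is not repeated. For the changes under other values, filters and limma settings the cause was not tested.

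With quantile normalization the counts were 28 for 100 µg/l at day 5, and for 1000 µg/l 0 at day 1, 80 at day 3, 0 at day 5, 11 at day 7, 64 on average and 45 for the difference between its days. With normexp background correction and the 75th percentile they were 0 for 100 µg/l at day 5, and for 1000 µg/l 0 at day 1, 10 at day 3, 0 at day 5, 3 at day 7, 8 on average and 0 for the difference between its days. The same setting gave 7 for 1000 minus 100 µg/l and 0 for the days of the controls. It also turned the sign of NEW_ruditapes_c1652_AS at day 1, to -0.22 ± 0.73. The median of all probes there was -0.33, and relative to it the change was 0.11, from which no direction can be read. With normexp and quantile normalization they were 28 for 100 µg/l at day 5, 25 for 1000 µg/l at day 7 and 45 for the difference between its days.

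With the authors' values the counts for 100 µg/l were 1 at day 1, 40 at day 5, 1 on average and 2 for the difference between its days. At 1000 µg/l they were 76 at day 3, 0 at day 5, 14 at day 7, 54 on average and 44 for the difference between its days. In the controls they were 34 for the days and 1 for day 7 minus day 1. With no filter on dim probes they were 19 for 100 µg/l at day 5, 68, 0 and 70 for 1000 µg/l at day 3, at day 5 and on average, 51 for the difference between its days and 9 for the days of the controls. With only probes well above background on all arrays they were 124 for 100 µg/l at day 5, 1 for the difference between its days, 0 and 71 for 1000 µg/l at day 1 and day 7, and 112 for the days of the controls. That setting tests fewer probes.

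With only the groups compared in the fit, which has fewer arrays, the counts for 100 µg/l were 2 at day 3, 2 at day 5 and 1 for the difference between its days. At 1000 µg/l they were 0 at day 1, 33 at day 3, 0 at day 5 and 1 at day 7. They were 142 for 1000 minus 100 µg/l, 10 for the days of the controls and 3 for control day 7 minus day 1. With array weights they were 186 for 100 µg/l at day 5, 0 and 162 for 1000 µg/l at day 1 and day 7, 152 for the difference between its days and 102 for the days of the controls. With a trend and robust estimation in limma every count stayed within 1.5-fold. With an added minimum log2 change of 1 they were 40 for 1000 µg/l on average and 55 for 1000 minus 100 µg/l. With an adjusted p under 0.10 they were 199 for 100 µg/l at day 5 and 1 for the difference between its days. For 1000 µg/l that threshold gave 304 at day 3, 125 at day 7, 220 on average and 215 for the difference between its days, with 408 for 1000 minus 100 µg/l and 289 for the days of the controls.

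With slide as a fixed block the count was 1 for 100 µg/l at day 1 and 0 for 100 µg/l at day 5. It was 0 for 1000 µg/l at day 1, 0 at day 3, 0 at day 5, 0 at day 7, 0 on average and 0 for the difference between its days. It was 0 for 1000 minus 100 µg/l and 0 for the days of the controls. That fit reversed ruditapesP_lrc10183 to -1.67 and ruditapesP_c15642 to -1.37 at 1000 µg/l on average, and ruditapesP_c5449 to 2.90 for 1000 minus 100 µg/l. By construction it compares arrays within slides, and the 7 arrays of slide 10 are its only link between 1000 µg/l and the other treatments. For the probes called at 1000 µg/l the median change in the called direction went from 1.42 (median SE 0.35) to 0.74 (0.68) at day 3, where 131 of 140 kept their direction. At day 7 it went from 1.21 (0.29) to 1.15 (0.57), where 46 of 46 did and 19 changed at least as much, so the larger error ended these calls together with, for the others, a smaller estimate. It went from 0.68 (0.17) to 0.44 (0.60) on average, where 83 of 106 did. For 1000 minus 100 µg/l it went from 0.72 (0.18) to 0.48 (0.54), where 188 of 221 did. Slide as a random block, with 1 correlation of 0.052 for all probes, also draws on differences between slides and cannot exclude them. With it the counts were 5 for 100 µg/l at day 5, 31 for 1000 µg/l at day 3, 24 at day 7, 31 on average and 35 for the difference between its days. They were 106 for 1000 minus 100 µg/l and 8 for the days of the controls. With scan day as a block they were 1 for 100 µg/l at day 1 and 1 at day 5. For 1000 µg/l they were 0 at day 1, 1 at day 3, 0 at day 5, 0 at day 7, 1 on average and 0 for the difference between its days. For 1000 minus 100 µg/l they were 0, for the days of the controls 0 and for control day 7 minus day 1 1. Without slide 10 they were 1 for 100 µg/l at day 5, and for 1000 µg/l 8 at day 5, 114 at day 7, 319 on average and 0 for the difference between its days.

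No strong pairing of samples by replicate number was seen: deviations of same-numbered arrays from their group means correlated across probes between -0.09 and 0.12 over 9 comparisons. Correlations over all probes cannot exclude that a number marks a shared aquarium or batch. With the replicate block, 1000 µg/l called 0 at day 1 and 29 at day 7.

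With each array left out in turn, the counts for 100 µg/l stayed at 0 at day 1, at day 7 and on average, and lay between 0 and 1 at day 3 (1 without control day 3 replicate 5). For control day 7 minus day 1 they lay between 0 and 1 (1 without control day 7 replicate 2). For the other comparisons, each array that moved the count over 1.5-fold is given with the count without it. The count for 100 µg/l at day 5 lay between 2 and 167. It was 3 without control replicate 1, 4 without replicate 3, 13 without replicate 4 and 125 without replicate 6, and 9 without 100 µg/l replicate 1, 11 without replicate 2, 167 without replicate 3, 117 without replicate 5 and 2 without replicate 6. The difference of the 100 µg/l effect between days gave counts that lay between 0 and 9. Leaving out arrays gave 9 without 100 µg/l day 1 replicate 5, 1 without 100 µg/l day 3 replicate 1, and 1 without 100 µg/l day 5 replicate 3 or 5. For day 1 of 1000 µg/l the count lay between 0 and 3. This became 0 without control replicate 1, 0 without replicate 2, 0 without replicate 4, 1 without replicate 6 and 0 without replicate 7, and 0 without 1000 µg/l replicate 3, 1 without replicate 4 and 0 without replicate 5. For day 3 of 1000 µg/l the count lay between 20 and 146. The values were 33 without control replicate 1, 65 without replicate 2, 25 without replicate 3 and 20 without replicate 4, and 27 without 1000 µg/l replicate 1, 55 without replicate 3, 52 without replicate 4 and 46 without replicate 5. For day 5 of 1000 µg/l the count lay between 0 and 5. Single arrays left out gave 0 without control replicate 1, 2, 3 or 4, and 0 without 1000 µg/l replicate 1, 1 without replicate 2, 5 without replicate 5 and 0 without replicate 6.

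For day 7 of 1000 µg/l the count lay between 1 and 113. It was 16 without control replicate 2, 1 without replicate 3, 2 without replicate 4 and 26 without replicate 6, and 28 without 1000 µg/l replicate 1, 113 without replicate 3, 6 without replicate 4 and 8 without replicate 5. The average over days of 1000 µg/l gave counts that lay between 58 and 177. Leaving out arrays gave 58 without control day 1 replicate 2, 59 without 1000 µg/l day 5 replicate 1 and 177 without replicate 3, and 70 without 1000 µg/l day 7 replicate 4. For the difference of the 1000 µg/l effect between days the count lay between 23 and 163. This became 35 without control day 5 replicate 1, 39 without replicate 3 and 42 without replicate 4, 63 without control day 7 replicate 4, 152 without 1000 µg/l day 3 replicate 2, 152 without 1000 µg/l day 5 replicate 1, 28 without replicate 2, 23 without replicate 3 and 41 without replicate 6, and 163 without 1000 µg/l day 7 replicate 3. For 1000 minus 100 µg/l the count lay between 138 and 299. The values were 138 without 100 µg/l day 1 replicate 3, 147 without 100 µg/l day 3 replicate 5, 143 without 1000 µg/l day 1 replicate 1, and 145 without 1000 µg/l day 5 replicate 1 and 143 without replicate 5. For the days of the controls the count lay between 5 and 96. Single arrays left out gave 9 without control day 1 replicate 2, 85 without replicate 4 and 96 without replicate 6, 16 without control day 3 replicate 3, 5 without control day 5 replicate 1, 10 without replicate 3 and 6 without replicate 4, and 31 without control day 7 replicate 3.

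The average change of ruditapesP_c17047 at 1000 µg/l lay between 1.62 and 1.75 when any 1 of 40 arrays was left out. Over the other alternatives its adjusted p lay between 4.92e-11 and 0.845, and the fixed slide block and the scan day block were the alternatives that ended the call. Over all probes the rule picked, including any not described in the text, and all alternatives, 540 estimates kept their direction and their call, 293 kept the direction only and 4 changed sign, with NEW_ruditapes_c1652_AS among the 4. Of the 293, 135 came from leaving out 1 array, 22 from normexp with the 75th percentile, 21 from the fixed slide block and 23 from the scan day block. Tests of gene lists and their alternatives were not run, because the lists matched 0 probes. Signal over background limits the named probes that were well above background on few arrays of a group.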

Other observations

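None of the tests with a stated expectation in this part was chosen after its result was seen, while the descriptions of contig pairs and of probes with separate levels were chosen after the data were examined.

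A change over days shared by the 3 treatments was tested by averaging the day effect over doses. limma called 24 of 9718 probes, with 1713 under an unadjusted p of 0.05, and 2 of 100 reassignments of arrays to days within doses gave as many, the real one included. The other reassignment with as many gave 107, several times the real count, which points to a structure of the samples. The fit with slide called 2 probes, and 1100 had an unadjusted p under 0.05. A day effect shared by the doses is consistent with the 2 of 100, but the count was lower with the slide term.

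The average changes at 100 and 1000 µg/l correlated at r = 0.42 across probes, which are not independent replicates, with a covariance of 0.10. Both doses are compared with the same controls, and a simulation in which the doses had no effect gave r = 0.50, between 0.47 and 0.54, with a covariance of 0.10. With a separate part of the controls for each dose the covariance averaged 0.00428 over 100 divisions of the controls, between -0.0266 and 0.0266, and was above 0 in 68% of them. The shared controls could therefore account for the correlation, and a small shared response was not excluded.

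704 pairs of tested probes carry the same contig number under different prefixes or suffixes. Their residuals after the group means were removed correlated at a median r of 0.26, against 0.00 for 2000 random pairs. The 19 pairs that differ only in a numbered suffix had a median of 0.98. The 170 pairs of a sense and an antisense probe of the NEW series had a median of 0.15. A second probe with the contig number of ruditapesP_c17047 rose by 1.59 ± 0.25 at 1000 µg/l on average over days, with an adjusted p of 1.37e-04 in limma. With slide in the fit its change was 0.60 ± 0.94 (adjusted p 0.943), so it shares the confounding of dose with slide.

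173 of 9395 probes had levels in separate groups of arrays, with a gap of at least 3 on the log2 scale and at least 6 arrays on each side. The median gap was 3.99 and the largest 9.16. Of the 14878 pairs of these probes, 32 correlated above 0.8, so the probes did not share 1 division of the arrays.

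The median GC content was 36.7% in the probes higher at 1000 µg/l on average, 38.3% in the lower and 36.7% in the probes not called. Across the 9718 probes, the correlation of GC content with the log2 change was 0.04 (Spearman).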
